A study of Mus musculus with 2 samples.

How the data were processed

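The series comprised 2 libraries from sorted muscle stem cells of Pax7-YFP knock-in mice, 1 from ChIP with an antibody against GFP and 1 from input DNA, grouped by the antibody and the title in the labels. There were no replicates, so no spread between libraries could be measured and nothing was tested between libraries. ChIP from cells without the YFP tag was not analysed here. Libraries were sequenced as single-end 50 bp tags, per the labels' protocols.

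GRCm38, bcl2fastq 2.16, HISAT2 and MACS2 2.1.1 were named per the submitters' processing notes, which give no role or order. Peaks were called as narrow peaks with MACS 2.1.1.20160309 at a q-value limit of 0.01, per the file headers. The effective genome size was 1.87e+09, the fragment length 172 bp, and local background windows were 1000 and 10000 bp, per the file headers. The redundant rate was 0.00 in both libraries per the file headers, so duplicate tags had been removed before the calling. After filtering, the ChIP library had 10622111 tags and the input 20429667, and the larger input was scaled to the ChIP depth (factor 0.5199), per the file headers. The deposited pileup is a coverage signal, the number of ChIP fragments over the summit, not scaled. The deposited fold enrichment is a ratio, (pileup + 1) over (local background + 1). The deposited −log10 p-value and −log10 q-value come from the caller's Poisson test. Positions are 1-based. Peaks were called on 1 library against 1 library, with no pooling.

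From the deposited values, the local background was recovered from the fold and the pileup, and the unscaled input by dividing it by the depth factor. The unscaled input is therefore the caller's local background before scaling, not always the input count at the summit. Some of its values were not whole numbers, such as 76.54 at Rn18s-rs5. A 95% interval for each fold was taken from the exact Poisson interval of its pileup with the background held fixed. Genes came from a table of GRCm38 genes with chromosome, start and end but without strand, exons or start sites. Genes whose coordinates belonged to scaffolds or patches were left out (348), and 21770 protein-coding genes remained. All 601 list members were matched, 3 of them by an older symbol.

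Tests, samples, gene lists, the rule for named genes and part of the alternatives were fixed before the data were examined. Because strand, exons and the genome sequence were not used here, the tests had to be changed after the files were seen. A transcription start site became either end of a protein-coding gene, the promoter share became the share of summits within 1000 bp of a gene end, and the intron share became the share inside a gene beyond that. A peak was assigned to the gene with the nearest end within 50 kb of its summit. An assignment by gene span had been looked at before this rule was settled. Random placement kept chromosome and width and ran from the lowest to the highest annotated coordinate, without gaps or mappability. Motif enrichment, fold enrichment by motif and the repeat filter were not run, and the 26 motifs that had been fixed were not used here.

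Shares were tested against 1000 placements (two-sided) and the 20 gene lists against 10000 placements (one-sided, for more), with Benjamini-Hochberg adjustment over the lists and a limit of 0.05. Lists were also set against 10000 random lists matched on the size of the territory nearest to each gene in 20 bins. Median folds were compared with a permutation test of 100000 resamples and a bootstrap of 2000. Chromosome counts were tested with the exact binomial test, and gene-end against distal peaks with Fisher's exact test. Shares carry Wilson 95% intervals. Peaks are not biological replicates, so all these p-values describe the list of these 2 libraries, and the intervals cover counting error only.

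The text names the 12 genes with the highest assigned folds, up to 4 genes per list with the highest folds, Pax7, Pax3, Myf5, Myod1, Myog and Myf6, and the 5 genes with the most peaks. Members of the muscle stem cell and immediate early lists beyond that rule were chosen after their values were seen. So were the unassigned peaks in Aopep and Etl4 and those nearest to Cdon and Lpar1. The peaks nearest to Otog and the genes at high-background peaks were chosen in the same way. Some genes that the rule names are not reported here.

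Alternatives fixed before were peaks at or above the median −log10 q, leaving out the 1% of peaks with the highest pileup, a gene-end window of 2500 bp, any overlap in place of the summit, assignment within 10 kb or without a distance limit, and Fisher's exact test over genes. Alternatives added after seeing the data were assignment by gene span, peaks moved by 100 to 500 kb, matched random lists, leaving out peaks within 1000 bp of a gene end, leaving out backgrounds of 10 or more, and expectation by gene ends for chromosomes. The comparisons by chromosome, by distance within lists and by gene family were also added after seeing the data.

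The list test was tested on simulated data over 21770 genes. It called 5 of 10 lists with 4 planted genes of 30, 10 of 10 lists with 8 planted genes, and 1 of 20 lists with none. The share test recovered 9.65 of 10 planted percentage points. Apart from the planted ones, simulated peaks were placed at random, just as in the tests. They lacked the preference for gene ends and the closeness of the real peaks. The rate of false calls in the real list is therefore not known from this simulation. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.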

Results

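Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out in muscle stem cells that were sorted by flow cytometry from C57BL/6 mice carrying a knock-in of yellow fluorescent protein (YFP) at Pax7. PAX7 is the paired box and homeodomain transcription factor that marks the resident stem cells of skeletal muscle. DNA fragments were recovered with an antibody against green fluorescent protein (GFP), and input DNA of the same kind of cells served as the control. There was 1 ChIP library with 10622111 tags and 1 input library with 20429667 tags after filtering, so no value had a replicate and the p-values describe these 2 libraries. The peak list held 2977 regions of GRCm38 called on the ChIP library against the input, and the series title names the question as the target genes of Pax7. Each peak's pileup (fragments over the summit), fold enrichment over the input and q-value were the authors', and the 95% intervals given with a fold were exact Poisson intervals of its pileup, which cover counting error only.

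Genes of the muscle stem cell list carried peaks more often than any other fixed list by share of members. Peaks were assigned to 15 of its 35 genes (42.9%, Wilson interval 28.0 to 59.1%), where random placement of the same peaks gave a mean of 3.73 genes. Ncam1, which encodes a cell adhesion molecule used as a surface marker of these cells, had 4 peaks, the strongest with a fold enrichment of 19.2 (13.7 to 26.3) at chromosome 9, 49827585 to 49827962, outside the gene and 28399 bp from its nearer end. Pax7 itself had a peak of 14.7-fold (9.92 to 21.0), the homeobox gene Dbx1 a peak of 14.2-fold (9.61 to 20.3) and Asb5 a peak of 12.3-fold (8.03 to 18.0). Calcr, the calcitonin receptor, reached 8.60-fold (5.13 to 13.6) at 23344 bp from its nearer end, inside the gene. The other genes of the list with a peak were Cav1, Sdc4, Vcam1, Musk, Itgb1, Edn3, Gas1, Fgfr4, Chrdl2 and Six4, with highest folds from 4.69 for Six4 to 11.6 for Cav1. The count was 4.02 times the placement mean, with the smallest p that 10000 placements can give (1e-04, one-sided permutation test) and adjusted permutation p = 0.001 over the 20 lists. Of the 35 genes, 17 also stood in another list.

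Immediate early genes, which respond within minutes to growth factors and stress, held peaks at 11 of 30 members (36.7%, 21.9 to 54.5%) against a placement mean of 1.91. Jun, a subunit of the AP-1 transcription factor, had the strongest, 17.7-fold (12.4 to 24.5) at chromosome 4, 95053155 to 95053420, 1050 bp from the nearer gene end. Socs3, a feedback inhibitor of cytokine signalling, had a peak of 10.6-fold (6.69 to 16.1) at 33623 bp, and the nuclear receptor gene Nr4a3 a peak of 8.82-fold (5.35 to 13.8) at 2293 bp. The peak of the heat shock gene Hspa1b, 8.60-fold (5.13 to 13.6), lay outside the gene, 773 bp from its nearer end. This peak may be uncertain because the neighbouring Hspa1a is nearly identical in sequence, but an effect of that on the peak was not tested. Atf3, Nr4a1, Zfp36, Dusp1, Fos, Fosb and Fosl2 made up the rest. The list stood at 5.74 times the placement mean, with adjusted permutation p = 0.001, again from the smallest p that the placements can give.

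Chromatin regulators and the control list of ribosomal and housekeeping genes also passed the placement test. Among the chromatin regulators, 10 of 35 genes had a peak against a mean of 3.85 (2.60 times, adjusted permutation p = 0.0173), led by Tet2 at 7.84-fold (4.61 to 12.6), Arid1a at 7.59-fold (4.38 to 12.4), Eed at 7.08-fold (4.01 to 11.8) and Kmt2a at 6.86-fold (3.88 to 11.4). Tet2 encodes a DNA demethylation enzyme, Eed a Polycomb subunit and Kmt2a a histone methyltransferase. In the housekeeping list 4 of 30 genes had a peak against a mean of 0.887 (4.51 times, adjusted permutation p = 0.0475). Among them were Rps19 at 10.1-fold (6.29 to 15.5) and Polr2a at 9.10-fold (5.51 to 14.3). Against random gene lists matched on the size of the surroundings nearest to each gene, a test chosen after the data were seen, the muscle stem cell list (adjusted permutation p = 0.001), the immediate early list (adjusted permutation p = 0.001) and the chromatin regulators (adjusted permutation p = 0.0220) passed and the housekeeping list did not (adjusted permutation p = 0.220). When only peaks at or above the median −log10 q were used, 2 chromatin regulators were left against a mean of 2.02 (adjusted permutation p = 0.954). Of the 10 alternative settings, planned and added, the chromatin regulators passed in 5, with ratios from 0.991 to 6.05 (assignment within 10 kb), and the housekeeping list passed in 5, with ratios from 1.58 (Fisher's exact test over genes) to 7.20 (assignment within 10 kb). The muscle stem cell list (2.08 to 6.72 times) and the immediate early list (2.69 to 12.2 times) passed in all 10. Without peaks within 1000 bp of a gene end, 6 chromatin regulators were left against 2.77 (adjusted permutation p = 0.168). The housekeeping list then had 1 gene against 0.611 (adjusted permutation p = 0.642). With moved peaks neither list passed (adjusted permutation p = 0.465 and 0.414). In the main test 6 of the 10 chromatin regulators and 3 of the 4 housekeeping genes had a peak within 1000 bp. Gene ends as a cause of both calls therefore remain open.

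Genes of the extracellular matrix and of cell adhesion had peaks at 11 of 39 members against a mean of 5.39 (2.04 times, adjusted permutation p = 0.0568), and the matched random lists gave adjusted permutation p = 0.0375. The list passed in 5 of the 10 alternative settings, with ratios from 1.33 without a distance limit to 3.35 in Fisher's exact test over genes. Besides Ncam1, the laminin gene Lamc1 reached 9.31-fold (5.72 to 14.4), the collagen gene Col1a1 9.31-fold (5.72 to 14.4) and the cadherin gene Cdh5 8.33-fold (4.97 to 13.2). In this list 0 of the 11 genes had a peak within 1000 bp of a gene end, and in the muscle stem cell list 1 of 15 did (Gas1), against 46.7% and 46.8% of the other genes with a peak. Both differences gave adjusted p = 0.00930 in Fisher's exact test (two-sided, 14 lists with at least 4 such genes), a comparison chosen after the data were seen. The exact test did not match genes on the size of their surroundings, so a part of that size in these differences was not tested. With peaks at or above the median −log10 q the matrix list was at adjusted p = 0.0700 in the exact test. Ncam1 and Itgb1 belong to both lists.

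**Figure D1:**
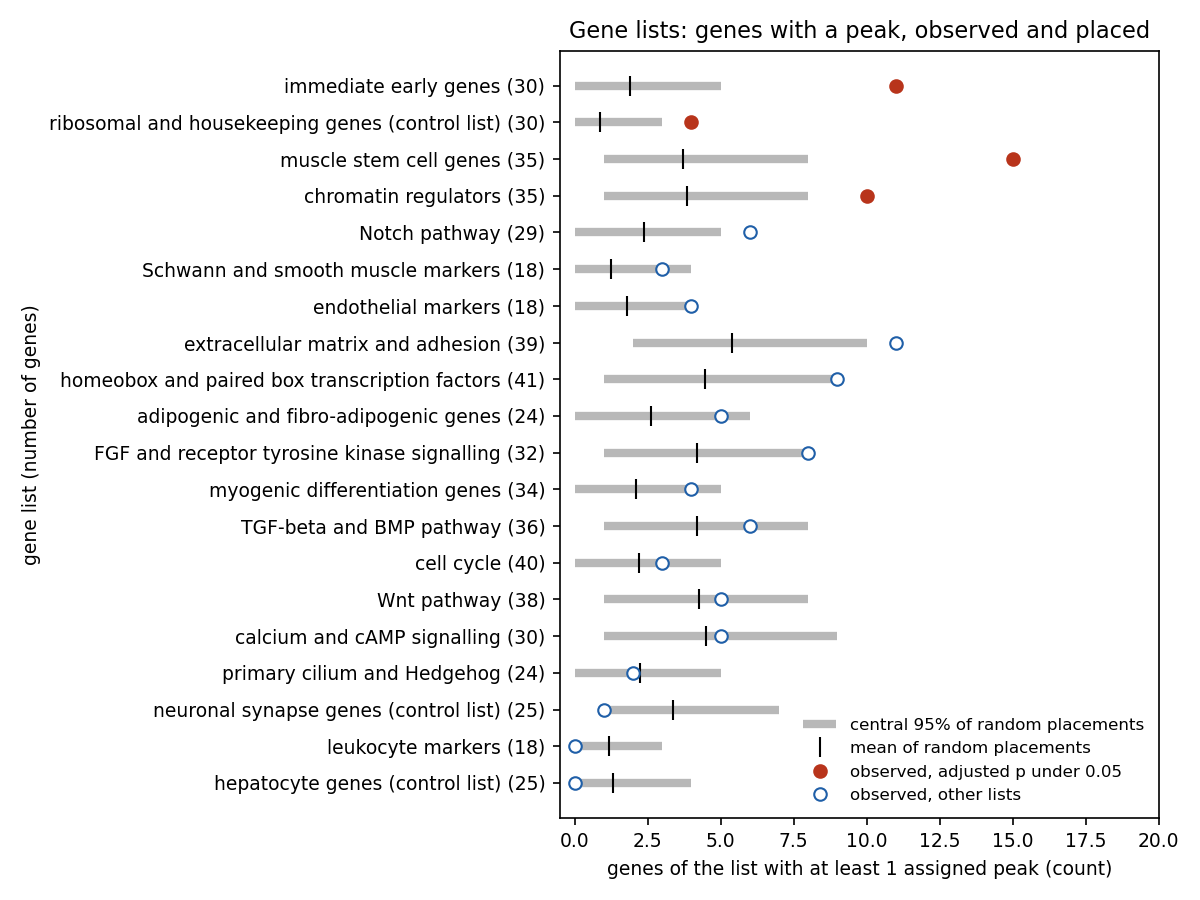
Number of genes with at least 1 assigned peak (horizontal axis, count) in each of the 20 gene lists (vertical axis, list size in parentheses). Circles are the observed counts, filled where adjusted p was under 0.05, ticks are the means and grey bars the central 95% of 10000 random placements. The muscle stem cell list at 15 genes and the immediate early list at 11 lie farthest beyond their bars, which end at 8 and 5.

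The remaining lists did not pass the main placement test after adjustment. Notch pathway genes had peaks at 6 of 29 members (mean 2.36, adjusted permutation p = 0.0803), with Dtx4 at 10.9-fold, Maml3 at 10.8-fold, the receptor gene Notch2 at 8.60-fold and Numb at 7.59-fold. Homeobox and paired box transcription factors had 9 of 41 (mean 4.47, adjusted permutation p = 0.0803), among them Prrx1 at 12.6-fold and Meis1 at 8.82-fold besides Dbx1. The homeobox list passed in 2 of the 10 alternatives, with ratios from 1.14 (no distance limit) to 2.96 (peaks at or above the median −log10 q). FGF and receptor tyrosine kinase genes had 8 of 32 (mean 4.20, adjusted permutation p = 0.115), with Spry2 at 10.1-fold, Igf1 at 9.33-fold, Spred1 at 7.08-fold and Erbb3 at 6.58-fold. The FGF list passed in 2 of the 10 alternatives, with ratios from 0.892 (peaks at or above the median −log10 q) to 5.32 (assignment within 10 kb). TGF-beta and BMP genes had 6 of 36 (mean 4.21, adjusted permutation p = 0.371), with Tgfbr3 at 13.2-fold, Smad3 at 12.3-fold, Smad6 at 9.13-fold and Bmp4 at 8.09-fold. Wnt pathway genes had 5 of 38 (mean 4.26, adjusted permutation p = 0.569), with Lrp6 at 8.60-fold, Fzd2 at 8.09-fold, Dkk2 at 6.47-fold and Ctnnb1 at 6.07-fold. Cell cycle genes had 3 of 40 (mean 2.21, adjusted permutation p = 0.553), namely Trp53 at 7.08-fold, Cdkn1b at 6.07-fold and Ccne1 at 5.86-fold. Genes of calcium and cAMP signalling had 5 of 30 (mean 4.50, adjusted permutation p = 0.594), with Nfatc2 at 13.7-fold, Pde4b at 7.84-fold and Pde10a at 6.47-fold besides Calcr, and with assignment by gene span the highest fold of Pde4b was 13.7. Genes of the primary cilium and Hedgehog signalling had 2 of 24 (mean 2.26, adjusted permutation p = 0.806), Cdon at 7.42-fold and Gas1 at 7.35-fold. The assigned Cdon peak lay 49069 bp from the nearer gene end. A stronger peak of 19.2-fold (13.7 to 26.3) was also nearest to Cdon, but at 59232 bp it was not assigned.

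Markers of other cells that a muscle sort could hold gave mixed counts, and none of these lists passed the main test. Endothelial markers had peaks at 4 of 18 genes (mean 1.81, adjusted permutation p = 0.210), which were Tek at 11.6-fold, Cdh5, Erg at 8.20-fold and Pecam1 at 6.58-fold. Schwann and smooth muscle markers had 3 of 18 (mean 1.25, adjusted permutation p = 0.225), Rgs5 at 14.7-fold, Erbb3 and Notch3 at 5.52-fold. Adipogenic and fibro-adipogenic genes had 5 of 24 (mean 2.60, adjusted permutation p = 0.210), among them the adipocyte regulators Cebpa at 11.6-fold and Pparg at 6.86-fold, with Cebpd at 6.07-fold and Ebf2 at 5.55-fold (10.1-fold with assignment by gene span). The adipogenic list passed in 1 of the 10 alternatives, with ratios from 0.727 (peaks at or above the median −log10 q) to 4.81 (assignment within 10 kb). Leukocyte markers had 0 of 18 (mean 1.18, adjusted permutation p = 1). Of the other control lists, hepatocyte genes had 0 of 25 (mean 1.31, adjusted permutation p = 1) and neuronal synapse genes 1 of 25, Snap25 at 5.47-fold (mean 3.36, adjusted permutation p = 1).

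Among the myogenic regulators, Pax7 and Myod1 had assigned peaks and Pax3, Myf5, Myog and Myf6 had none. The Pax7 gene lies at chromosome 4, 139737059 to 139833530, and held 2 peaks within its span. The stronger lay at 139772599 to 139772954 with a pileup of 28 and a fold of 14.7 (9.92 to 21.0), and the weaker at 139821525 to 139821715 with a pileup of 15 and a fold of 8.09 (4.75 to 13.0). Whether they fall in exons or introns was not analysed here. Myod1, which encodes the myogenic determination factor MyoD, lies at chromosome 7, 46376474 to 46379092. Its assigned peak at 46348843 to 46349147 was 27.5 kb from the gene, outside any protein-coding gene, with a fold of 9.10 (5.51 to 14.3). In all, 3 peaks lay within 100 kb of Myod1, and the other two were nearest to Otog, with folds of 9.31 and 11.8. No peak lay within 100 kb of Pax3, Myf5, Myog or Myf6, where the nearest summits were 141.4, 175.6, 264.6 and 167.8 kb away. Myogenic differentiation genes as a list had peaks at 4 of 34 members (1.90 times the placement mean, adjusted permutation p = 0.251), namely Myod1, Ryr1 at 7.35-fold, Mylpf at 6.47-fold and Myh1 at 6.07-fold.

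**Figure D2:**
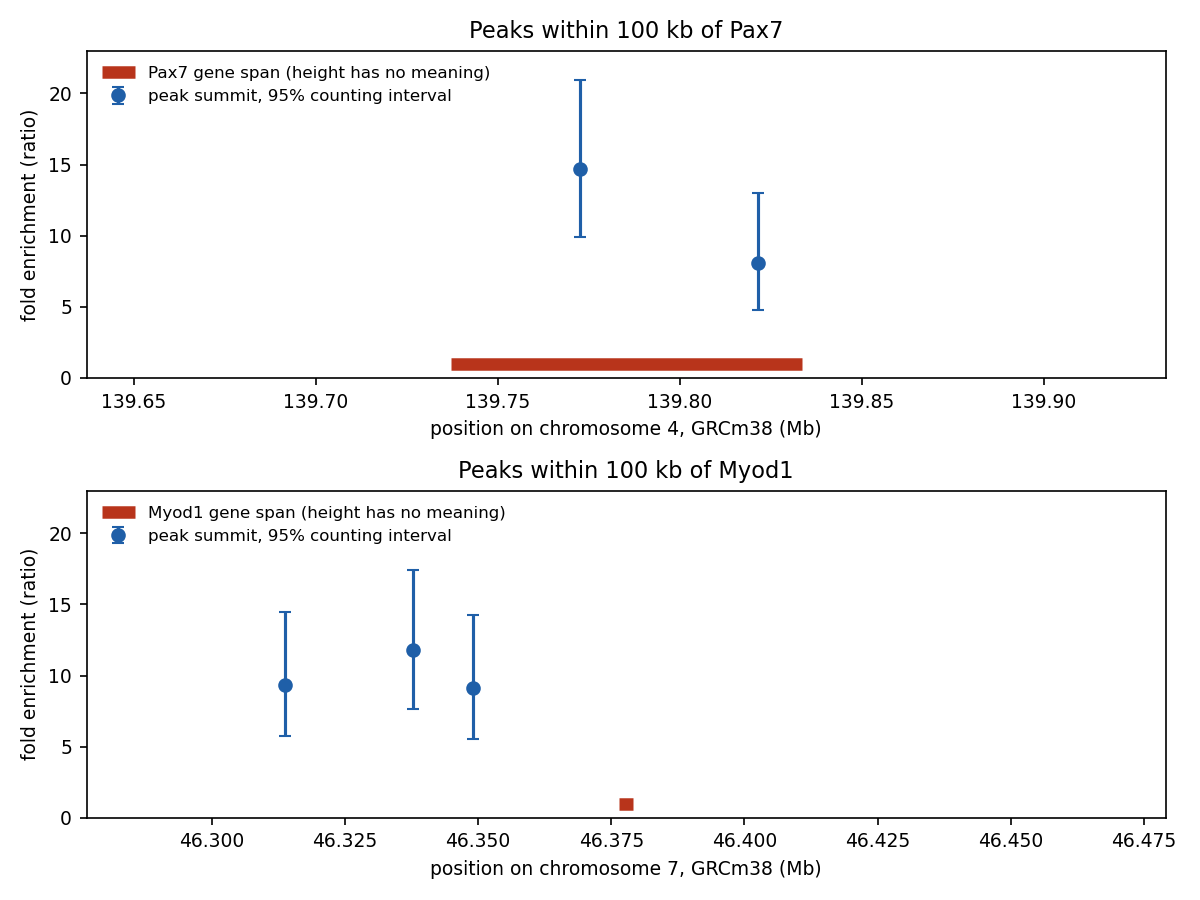
Peaks within 100 kb of Pax7 and of Myod1, with position on the chromosome in Mb on the horizontal axis and fold enrichment over input on the vertical axis. Points are summits with 95% Poisson intervals of the pileup, and red bars are the gene spans. The Pax7 span holds 2 peaks, at 14.7-fold and 8.09-fold, and 3 peaks lie to the lower-coordinate side of Myod1.

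The strongest assigned peak belonged to Dpy19l3, which encodes a C-mannosyltransferase, with a fold of 24.0 (17.8 to 31.7) inside the gene at chromosome 7, 35747500 to 35747937; without the 1% of peaks with the highest pileup its highest fold was 8.33. Mogat1, a monoacylglycerol acyltransferase gene, followed at 19.7-fold (14.1 to 26.9) and also inside the gene. Nhlrc1 at 19.2-fold, Dusp23 and Zfp408 at 18.2-fold, Spsb1 and Mphosph8 at 17.2-fold and Rabl3 at 16.7-fold had their summits within 225 bp of a gene end. Gorab at 16.7-fold and Pdpn, which encodes podoplanin, at 16.2-fold had theirs inside the gene. The peaks with the highest folds of the list were not assigned because they lay beyond 50 kb from a gene end. They stood inside Aopep at 27.3-fold (20.6 to 35.6), chromosome 13, 63113116 to 63113599, and inside Etl4 at 25.3-fold (18.8 to 33.3), chromosome 2, 20642690 to 20643194. The genes with the most assigned peaks, 5 each, were Prrx1, Gxylt2, Lpar1, Mdfic and Nfkb1, with highest assigned folds of 12.6, 11.1, 10.2, 9.80 and 9.31. A stronger unassigned peak of 21.2-fold was nearest to Lpar1, at 109863 bp. Some assigned peaks were close neighbours, and whether they belong to the same enriched region was not tested. Prrx1 had peaks at 163221595 to 163222174 and 163222331 to 163222523, and Gxylt2 at 100731961 to 100732360 and 100732438 to 100732938.

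Of the 2975 peaks on assembled chromosomes, 2161 (72.6%) were assigned to 1832 of 21770 protein-coding genes (8.42%), and 1572 of these genes had 1 peak. The median fold enrichment of the 2977 peaks was 7.35 (quartiles 6.27 and 8.82), 430 reached 10-fold and 6 reached 20-fold. The median pileup was 15 fragments and the median width 230 bp, so that a typical peak rested on few fragments. At 1313 peaks (44.1%) the input background was at its floor of 0.977 fragments.

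Ends of protein-coding genes were the favoured location. Summits lay within 1000 bp of a gene end in 866 of 2975 peaks (29.1%, Wilson interval 27.5 to 30.8%), which was 9.26 times the 3.14% of random placement. Peaks inside genes beyond that distance made up 36.4% (34.7 to 38.1%) against 39.3% placed, and intergenic peaks 34.5% (32.8 to 36.2%) against 57.5% placed. Each difference had p = 0.001 in a two-sided permutation test, the smallest that 1000 placements can give. The shares make up the whole, so the excess at gene ends lowers the others. The lower share inside genes therefore does not show that genes were avoided. With gene-end peaks counted too, 1473 of the 2975 peaks (49.5%) lay inside a protein-coding gene. Start and end of a gene were not told apart, since strand was not used here. No difference in strength between gene-end peaks and the others was detectable, with a median of 7.24-fold against 7.35-fold (difference −0.118, bootstrap interval −0.341 to 0.118, permutation p = 0.355).

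**Figure D3:**
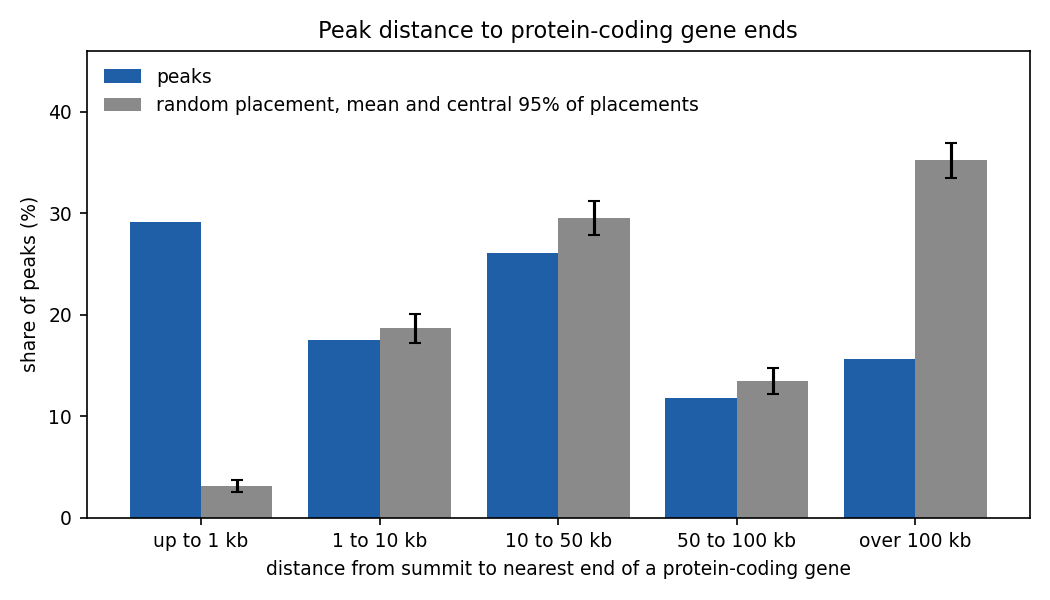
Share of the 2975 peaks (vertical axis, percent) by distance from the summit to the nearest end of a protein-coding gene (horizontal axis, bins in kb). Blue bars are the peaks, grey bars the mean of 1000 random placements with the central 95% of placements. Within 1 kb the peaks hold 29.1% against 3.14%, and beyond 100 kb 15.6% against 35.2%.

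The X chromosome held 17 peaks where its annotated length gave 194 (ratio 0.0876, adjusted p = 1.73e-61, exact binomial test over 20 chromosomes) and its number of gene ends gave 133 (ratio 0.128). Bcor, a gene for a transcriptional corepressor, was nearest to 3 of them, the strongest at 10.6-fold, and Ftsj1 had a peak of 10.1-fold (genes chosen after their values were seen). On the autosomes the ratio to the length expectation ran from 0.674 on chromosome 14 to 1.66 on chromosome 19. Chromosomes 9, 10, 11, 17 and 19 held more peaks than their length gave and chromosomes 6 and 14 fewer, at adjusted p from 5.06e-06 for chromosome 19 to 0.0491 for chromosome 9 (exact binomial test). Expectations by length or by gene ends were shares of a total that included X. The low X count therefore raised all autosomal ratios, and chromosome 9, close to the limit of 0.05, is uncertain. The test also took peaks as independent, although 14.6% had another summit within 10 kb. By number of gene ends the autosomal pattern was another, as chromosome 11 turned to 0.826 and chromosome 7 went from 1.13 to 0.664, the lowest autosome (adjusted p = 3.74e-09, exact binomial test), while chromosomes 1 and 12 rose to 1.52 and 1.61. Chromosomes 6 (adjusted p = 0.180), 9 (0.898), 14 (0.0525), 17 (0.898) and 19 (0.180) no longer passed this exact test. Chromosome 10 was above both expectations (1.29 and 1.37) and X below both. The median pileup was 13 fragments for X peaks and 15 for autosomal peaks. The Y chromosome held 0 peaks. Placement ranges came from the annotated genes and did not account for gaps or for sequence that short tags cannot reach.

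**Figure D4:**
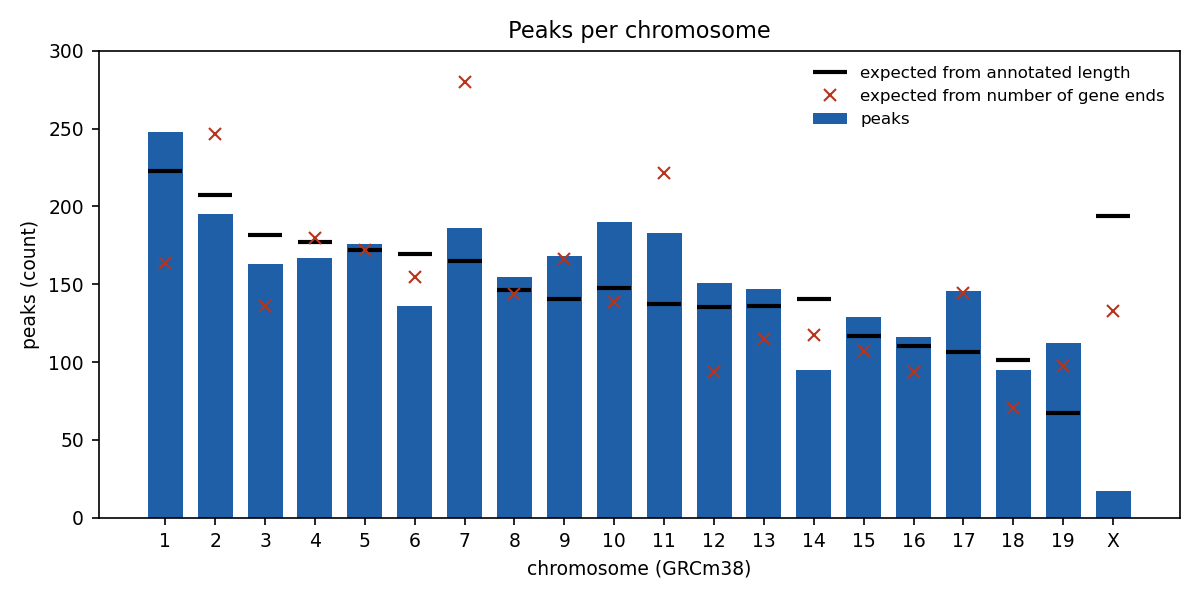
Number of peaks (vertical axis) on each chromosome of GRCm38 (horizontal axis). Bars are the observed counts, black dashes the counts expected from annotated length and crosses those expected from the number of gene ends. The X chromosome holds 17 peaks, below both marks at 194 and 133.

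A small group of 25 peaks stood on a scaled input background of 10 fragments or more, while the highest background elsewhere was 4.16. Their folds ran from 1.42 to 5.81, with a median of 2.59 against 7.35 for the other peaks. The widest was at the ribosomal RNA pseudogene Rn18s-rs5, chromosome 17, 39842971 to 39848892, with a pileup of 236 and a fold of 5.81. Others lay inside Lars2 (2.89-fold), Cdk8 (3.98-fold), Zc3h7a (3.80-fold) and Camk1d (3.66-fold), and clusters of 4 peaks each lay on chromosome 2 from 98662245 to 98667279 and on chromosome 14 from 19416283 to 19419380. With duplicate tags removed and fragments of 172 bp, no position can carry more than 344 fragments. At the peak with the deepest input, on chromosome 14, the unscaled input reached 344 and the ChIP pileup 337. In 11 of the 25 peaks the unscaled input was 100 fragments or more, and there the ChIP pileup was 0.947 times the unscaled input (median, range 0.739 to 1.08), while in the other 14 it was 2.01 times (1.15 to 3.08).

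**Figure D5:**
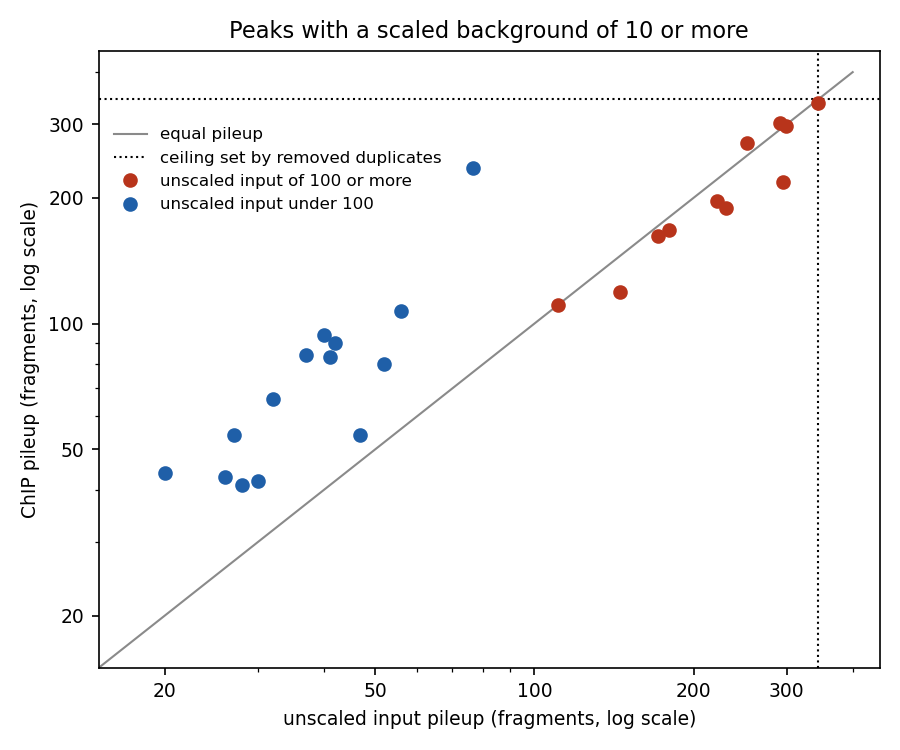
ChIP pileup (vertical axis, fragments, log scale) against the unscaled local input background at the 25 peaks with a scaled background of 10 fragments or more. The horizontal axis (fragments, log scale) labels this background as unscaled input pileup. The grey line marks equal pileup and dotted lines the ceiling of 344 fragments. The 11 peaks in red, with an unscaled input of 100 or more, lie near the grey line, and the 14 in blue lie above it.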

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

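All tests in this part were chosen after the results were seen. Signal on unplaced scaffolds lay outside the tests by gene, distance and chromosome, but it entered the medians over all 2977 peaks. A scaffold peak at 21961 to 22137 had a fold enrichment of 1.57 and a pileup of 119, and a peak at 59878 to 60049 of another scaffold had a fold enrichment of 2.17 and a pileup of 54. Both belong to the 25 peaks with a scaled background of 10 fragments or more.

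Removal of duplicate tags is a candidate explanation for the low-fold calls in that group, since a capped pileup in the deeper input is then scaled down to 0.5199 of its height. It needs a ChIP pileup of about the unscaled input. In the 11 peaks with an unscaled input of 100 or more, the median ratio was 0.947, and at a ratio of 1 the scaling alone gives 1.92. The input was at the ceiling of 344 fragments in 1 of these 11 peaks and at 299 or less in the other 10, and a real enrichment of about 1.92 would give the same ratio, so the 2 cannot be told apart. In the other 14 peaks, which include Rn18s-rs5, Lars2 and Cdk8, the median ratio was 2.01 and the lowest 1.15. This argues against a cap for most of them, but the ratio alone leaves the lowest open. The unscaled input of these 14 peaks was 20 to 76.5 fragments, so none was at the ceiling of 344. No biological explanation was tested.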

How the results depend on the processing

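The number of lists past the test was 4 in the main analysis, 2 with peaks moved by 100 to 500 kb (added after seeing the data) and 2 without a distance limit, and both of those were among the 4. It was 6 with assignment within 10 kb, where the FGF and adipogenic lists joined the 4, and 6 in Fisher's exact test over genes, where the matrix, FGF and homeobox lists joined and the housekeeping list was lost, and from 3 to 5 in the other settings. With peaks at or above the median −log10 q there were 1501 peaks, the chromatin regulators turned to 0.991 times the placement mean (adjusted permutation p = 0.954), and the share of matrix and adhesion genes with a peak within 1000 bp stayed at 0 times that of other genes with adjusted p = 0.0700 in Fisher's exact test. Fewer peaks entered that setting, and otherwise the cause was not tested. The other 66 alternative values of the main results kept their side of the threshold or, for counts, stayed close. Tested ratios among them kept their direction, while the direction of the fold difference between gene-end and other peaks was not compared. Among the counts, the number of chromosomes past the test was 8 in the main analysis, 6 or 7 with peaks left out and 11 by number of gene ends. The chromosomes themselves changed more than this count. By gene ends only chromosomes 10 and X kept their call, and chromosome 11 turned from 1.33 to 0.826. Chromosomes 6, 9, 14, 17 and 19 were lost, and 1, 2, 3, 7, 12, 13, 16 and 18 were new. Among single lists and named genes 10 alternative values became significant, 10 no longer were (1 of them the reversed one above) and 3 folds moved. Of 200 alternative ratios of lists, 14 lay on the other side of 1 from the main ratio, in 8 lists of which 1, the chromatin regulators, had passed the main test, and 21 of the 75 named genes had no peak at or above the median −log10 q. The motif tests and the repeat filter were not run, as the genome sequence was not used here. No paired analysis was possible because each group had 1 library. The median pileup was 15 fragments and no peak had fewer than 9, and whether more depth would add peaks was not tested.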

Other observations

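The tests in this part were chosen after the results were seen. Families of chemosensory receptor genes carried few peaks. Olfactory receptor genes (Olfr) had an assigned peak at 4 of 1109 members, where random gene lists matched on territory gave 61.0, and vomeronasal receptor genes (Vmn) at 1 of 352 against 28.6. Predicted genes with a Gm symbol had 23 of 1323 against 117. Each had the smallest p of 1e-04 that 10000 draws can give (one-sided permutation test for fewer) and adjusted permutation p = 0.0110 over 330 tests of 165 symbol stems. The draws took genes as independent. They accounted neither for members of a family that lie next to each other nor for sequence that short tags cannot reach. These p-values may therefore overstate the evidence. For more peaks, 0 stems passed the adjusted test and 9 had an unadjusted p under 0.05 (permutation test). Peaks also lay close together, as 434 (14.6%) had another summit within 10 kb, against 2.48% for placed peaks (permutation p = 0.001, the smallest that 1000 placements can give).

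The muscle stem cell and immediate early lists held peaks more often than placement gives. A general pull-down of gene ends would end the call once peaks within 1000 bp of any gene end are left out. Without them 14 muscle stem cell genes had a peak against 2.66 and 7 immediate early genes against 1.36, both at adjusted permutation p = 0.00200. For the muscle stem cell list this restates that 14 of its 15 genes had only farther peaks, which argues against gene ends as the whole cause. In the immediate early list the peaks of Jun, Zfp36, Nr4a3 and Fosb lay only 1050 to 2454 bp from a gene end. A limit of 1000 bp therefore cannot decide the question for that list. A rich or easily mapped region that reaches over 100 to 500 kb would give peaks moved by that distance the same counts. The moved peaks gave means of 7.23 and 3.35 against 15 and 11, both at adjusted permutation p = 0.00500. For the muscle stem cell list this argues against such a broad region as the whole cause, although the moved means were above those of placement. The moves did not keep peaks near gene ends, and 5 of the 11 immediate early genes had a peak within 1000 bp. The comparison therefore cannot decide the question for the immediate early list. Rich or easily mapped neighbourhoods narrower than 100 kb were not tested. Open chromatin in these cells, a response to sorting and binding by PAX7 all remain open as hypotheses, and none was tested.

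The X chromosome held 17 peaks. If cells with 1 copy of X gave halved pileups, the X count could fall to the density of autosomal peaks with a pileup of at least 18, which is 2 times the lowest called pileup of 9. That density gives 54.4 X peaks, and the sparsest autosome by this measure, chromosome 6, gives 27.5. The 17 observed lay below both and differed from the density of all autosomes (p = 1.51e-08, exact binomial test). Against chromosome 6 (24 peaks) no difference was detectable (p = 0.158, exact binomial test). Chromosome 6 was picked as the lowest autosome in these same counts, and with so few peaks this comparison could hardly show a difference. It therefore decides nothing. A halved pileup is not excluded, though both densities lie above the count, and it cannot be told apart from other causes by these counts. A low number of gene ends predicts no gap among distal peaks, yet 13 distal X peaks stood against 138 by length (p = 9.46e-44, exact binomial test), which argues against it as the whole cause. Sequence that short tags cannot reach was not tested, the labels used here give no sex of the mice, and no biological explanation was tested.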
